A study of Mus musculus with 131 samples.

How the data were processed

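Chromatin immunoprecipitation with sequencing (ChIP-seq) was done in mouse embryonic stem cells (ESC, day 0, grown in 2i/LIF medium) and in epiblast-like cells derived from them (EpiLC, day 2). The 131 samples comprise ChIP libraries for 5 targets (the insulator protein CTCF and the histone marks H3K4me1, H3K4me3, H3K27ac and H3K27me3) and 12 inputs, libraries of chromatin before immunoprecipitation. They come from 4 cell lines. TET_KO lacks Tet1, Tet2 and Tet3, and DNMT_KO lacks Dnmt1, Dnmt3a and Dnmt3b, per the labels. Each was compared with its own wild-type line, TET_WT or DNMT_WT. Every line, stage and target had 3 libraries, except H3K27me3 in TET_WT ESC with 2, and inputs were present for the DNMT lines only. The labels do not say whether replicates were separate cultures, so all p-values measure the spread between these samples. Each genotype is a single line.

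Reads were trimmed with Trim Galore 0.6.5 and cutadapt 2.3 and aligned with Bowtie2 2.4.1 to the mouse genome build GRCm38, per the submitters' processing notes. The authors deposited log2 RPKM values (reads scaled to tile length and library size) in 1362779 adjoining tiles of 2 kb, with 1 column per library. In each column, 2 to the power of the value was a whole multiple of the value of 1 read, within 0.01 reads, in at least 99.994% of the tiles. Tiles without reads were stored as 0.9 reads. Reads per tile were recovered from this step, and their sum gave the depth. Which library total the authors divided by, and how reads were filtered, is not stated. The spread between replicate libraries exceeded counting error in every pair (lowest chi-square per degree of freedom 1.119), so limma was run on the log2 values and not a test for counts. All 131 columns were matched to a sample.

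Genes came from the RefSeq annotation of the same build, which gives start and end but no strand. The promoter was therefore taken at the gene end with the higher H3K4me3. A tile was tested for a target when its mean over that target's libraries stood at least 1 log2 unit above the mean of the 12 inputs, and the input mean was at least -3, a level that 1225405 tiles reached. The inputs of the DNMT lines served for the TET lines as well. Tested tiles numbered 43473 for CTCF, 125058 for H3K4me1, 38384 for H3K4me3, 78181 for H3K27ac and 52812 for H3K27me3. Each library was shifted to the same median over the tested tiles of its target. For H3K4me3, H3K27ac and H3K27me3 a gene's value was the mean of all tiles within 2 kb of its promoter that reached the input minimum. Such a gene was kept when the mean of these tiles over the target's libraries stood at least 1 log2 unit above that of the inputs. For H3K4me1 the value was the mean of the tested tiles within the gene and 20 kb on either side. This gave 10927 genes for H3K4me3, 9699 for H3K27ac, 3101 for H3K27me3 and 17570 for H3K4me1.

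Differences were tested with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend) in R 4.3.3, with the means of the 8 groups of a target as coefficients. Each knockout was compared with its own wild-type line in ESC and in EpiLC. The other comparisons were EpiLC against ESC averaged over the wild-type lines, and the difference of a knockout's effect between the stages. A tile or gene passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. Only such tiles and genes are said to rise, fall or change. Differences are given with the standard error of the fit (SE) and group means with the standard deviation (SD) over libraries. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and data.table (version 1.17.8), and figures drawn with matplotlib 3.10.9.

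The 14 gene lists hold 315 genes, of which 314 were in the annotation. They are naive pluripotency, formative and primed pluripotency, germline genes with CpG-rich promoters, 2-cell-like genes, imprinted genes, Hox clusters, haematopoietic and endothelial genes, mesoderm, neuroectoderm, primitive and definitive endoderm, trophoblast, fibroblast (feeder) genes, housekeeping genes and the 6 targeted genes. Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over all lists and the 5 comparisons of a target. In every list and comparison, as many members passed when p was adjusted over the list alone as when it was adjusted over all genes. With an estimated correlation, 3 of the 59 passing list results still passed.

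Genes named in the text were chosen by a rule. It takes, per histone mark and comparison, up to 2 genes with the largest rise and 2 with the largest fall among genes that passed, without predicted or cloned-transcript names and without olfactory and vomeronasal receptor families. It adds up to 2 passing members of each list per mark, the 6 targeted genes, and for CTCF up to 2 tiles each way. Genes chosen otherwise are described as chosen after their values were seen. The test was tested on data simulated for each target from every tile's mean and within-group SD over all its libraries. Noise was normal and independent between libraries, and changes were added to the TET_KO EpiLC libraries. Differences in enrichment between libraries were not simulated, so the rates below do not cover them. Of 100 tiles changed by 1.5 log2 units it recovered 99% for CTCF, 95% for H3K4me1, 95% for H3K4me3, 97% for H3K27ac and 87% for H3K27me3, and of 100 tiles changed by 3 units it recovered 100% for each target. False calls numbered 3, 2, 2, 4 and 8 in that order, and the unchanged comparisons gave 0 calls by limma.

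Alternatives were the values as deposited without a shift, quantile normalization, a pseudocount of 0.5 RPKM, no enrichment minimum, the replicate number as a block, centring each chromosome of each library, and leaving out each library in turn. The groups, comparisons, tests, thresholds, lists, naming rule and these alternatives were fixed before the data were examined. A pair of alternatives was chosen after seeing the data. The first leaves out libraries whose contrast of tested over other tiles was under 0.65 times the median for the target and line pair. The other leaves out replicate 2 of both genotypes in DNMT EpiLC. Reads per tile over the targeted genes checked the genotype labels. The log2 ratio of each chromosome's mean RPKM to that of the autosomes, outside the tested tiles, checked copy number. Embryoid bodies, named in the series description, are not analysed here.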

Results

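The series asks how the gain and loss of DNA methylation shape regulatory chromatin when pluripotent cells leave the naive state. The targets were CTCF, which binds insulators, and the marks H3K4me1 (enhancers), H3K4me3 (promoters), H3K27ac (active elements) and H3K27me3 (Polycomb repression). They were measured in TET_KO, DNMT_KO and their wild-type lines as ESC and as EpiLC. Each of the 40 groups of line, stage and target held 3 libraries, except H3K27me3 in TET_WT ESC with 2, and the 4 groups of inputs held 3 each. Unless stated, n is therefore 3 libraries per group, values are log2 RPKM after the shift to a common median, errors of differences are SE and errors of group means are SD. Tile reads per library, in units of 1e6, ran from 15 to 63.4 for CTCF (median 24.5), 20.6 to 475.3 for H3K4me1 (median 29.65), 23.9 to 327.6 for H3K4me3 (median 64.9), 17.9 to 353 for H3K27ac (median 51.45), 15.7 to 147.1 for H3K27me3 (median 22.4) and 13.8 to 32.7 for inputs (median 24.35). In the TET libraries of H3K4me3, H3K27ac and H3K27me3, 16.9% to 43.7% of the tiles with under 50 reads held an odd number of reads, against 50.3% or more in all other libraries. Many reads of those TET libraries thus appear to be counted in pairs, and their depths are not comparable with the others. The correlation across tiles between replicate libraries was 0.6099 to 0.7878 for CTCF, 0.6798 to 0.923 for H3K4me1, 0.7447 to 0.8922 for H3K4me3, 0.8101 to 0.9285 for H3K27ac and 0.5602 to 0.9239 for H3K27me3, where tiles are not independent replicates.

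The targeted genes were read first, as reads in the 2-kb tile with the lowest ratio of knockout to wild type in the pooled CTCF and H3K27me3 libraries. In Tet1 (chromosome 10, 62804570 to 62887469) the tile at 62812001 to 62814000 held 171 reads in TET_WT and 0 in TET_KO. All 6 TET_KO libraries had 0 reads there for CTCF, for H3K4me1 and for H3K27me3, and at most 7 for H3K4me3 and 1 for H3K27ac, while TET_WT libraries had 13 to 23 for CTCF, 65 to 159 for H3K4me3 and 125 to 260 for H3K27ac. In Tet2 (chromosome 3, 133463677 to 133545136) the tile at 133470001 to 133472000 fell from 141 to 8 pooled reads, a log2 ratio of -4.66 at equal depth. H3K4me3 reads in that Tet2 tile remained, at 26 to 67 per TET_KO library and 18 to 50 per TET_WT library. In Tet3 (chromosome 6, 83362373 to 83457208) the lowest tile, 83372001 to 83374000, held 464 and 334 reads, a log2 ratio of -1.15, and its H3K27ac reads were 3 to 20 in TET_KO libraries and 34 to 109 in TET_WT libraries. The TET labels thus matched the reads over Tet1 and Tet2 in every library tested for CTCF. Over Tet3 the ranges overlapped for CTCF, 5 to 16 reads in TET_KO and 8 to 26 in TET_WT, and for H3K27me3, 21 to 92 and 50 to 104, so a deletion there was not settled. In the DNMT lines the lowest tile ratios were -0.20 in Dnmt1, -0.29 in Dnmt3a and -0.27 in Dnmt3b, so no loss of 2 kb was seen and these tiles do not check the DNMT_KO label.

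**Figure D1:**
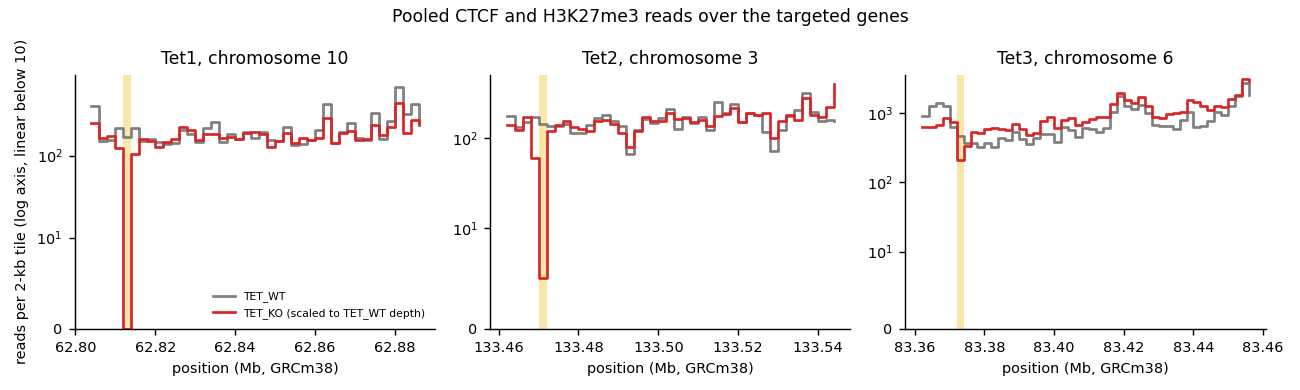
Pooled CTCF and H3K27me3 reads per 2-kb tile (log axis, linear below 10) along Tet1, Tet2 and Tet3 against the position in Mb on GRCm38, for TET_WT (grey) and TET_KO (red, scaled to TET_WT depth). The yellow tile is the lowest of each gene, with 0 TET_KO reads in Tet1, 8 in Tet2 before scaling, and 334 in Tet3.

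The lines also differed in copy number. It was measured in the CTCF libraries as the log2 ratio of a chromosome's mean RPKM to that of the autosomes, outside the tested tiles of all targets. Chromosome 8 stood at 0.475 ± 0.006 in TET_WT ESC and 0.001 ± 0.003 in TET_KO ESC, and chromosome 14 at 0.344 ± 0.012 and -0.034 ± 0.015 (exact permutation p = 0.1 each, two-sided, the smallest that 3 against 3 allow). The same differences were seen in EpiLC, at -0.493 for chromosome 8 and -0.384 for chromosome 14, and chromosome 6 was lower by a smaller amount, -0.146. Chromosome Y was higher in TET_KO, by 1.04 in ESC and 0.96 in EpiLC. In the DNMT inputs chromosome 8 stood at 0.506 to 0.509 in every group.

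The numbers of changed tiles by target and comparison differed widely between the TET and DNMT lines, as the bar plot of changed tiles shows. Enrichment differed between the line pairs too. For H3K27me3 the contrast of tested over other tiles was 1.769 to 2.363 in TET libraries and 0.585 to 1.451 in DNMT libraries. The DNMT EpiLC groups also hold the libraries labelled replicate 2, described under the DNMT lines. Changes were simulated in TET_KO EpiLC only, so these counts do not rank the knockouts. The shift to a common median of each library changed the median difference over all tested tiles, toward 0 in most comparisons and away from it in others. Without that shift this median difference was -0.36 for CTCF in TET_KO ESC, -0.67 in TET_KO EpiLC, 0.35 in DNMT_KO ESC, 0.20 in DNMT_KO EpiLC and 0.46 for EpiLC against ESC. It was -0.18 for H3K4me1 in TET_KO EpiLC, -0.11 in DNMT_KO ESC and -0.66 in DNMT_KO EpiLC. For H3K27ac it was -0.36 in TET_KO ESC, -0.33 in TET_KO EpiLC, -0.13 in DNMT_KO EpiLC and -0.20 for EpiLC against ESC, the last being 0.19 after the shift. H3K4me3 moved from 0.04 to -0.19 in TET_KO EpiLC and from 0.11 to -0.11 for EpiLC against ESC. H3K27me3 moved from -0.14 to 0.11 in TET_KO EpiLC, and stood at -0.37 in DNMT_KO ESC and -0.15 for EpiLC against ESC without the shift. All changes are relative to the shifted median.

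**Figure D2:**
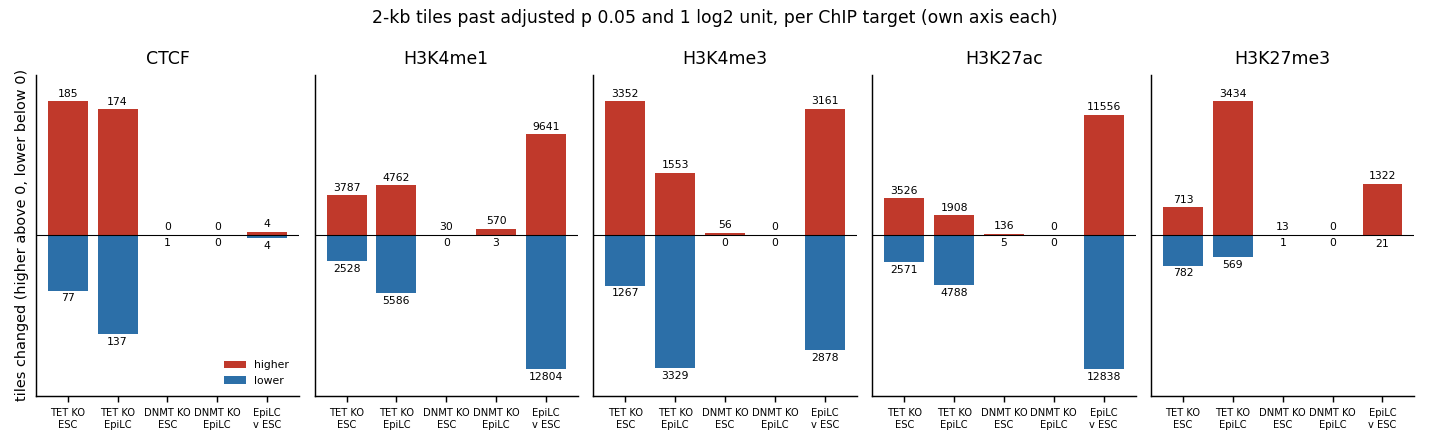
Tiles of 2 kb higher (red, above 0) or lower (blue, below 0) in each comparison, one panel per target with its own axis, counted at adjusted p under 0.05 and 1 log2 unit. H3K27me3 rose in 3434 tiles and fell in 569 in TET_KO EpiLC, while DNMT_KO EpiLC had 0 calls by limma for H3K4me3, H3K27ac, H3K27me3 and CTCF, with 549, 3505, 4899 and 522 tiles at an unadjusted p under 0.05.

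Differentiation of wild-type cells to EpiLC lowered marks at genes of the naive state and raised them at genes of the formative state. H3K27ac at the promoter of Tfcp2l1, a transcription factor of naive cells (chromosome 1, 118624001 to 118630000), fell by 3.69 ± 0.10 (adjusted p = 1.07e-22), from 4.33 ± 0.13 to 1.08 ± 0.24 in TET_WT. H3K4me3 at Tdh, a threonine-degrading enzyme of naive ESC metabolism, fell by 3.72 ± 0.12 (adjusted p = 2.38e-17). H3K27ac rose at Dnmt3l, the cofactor of the de novo methyltransferases, by 3.59 ± 0.17 (adjusted p = 2.94e-17) and at Sall2, a zinc-finger factor of the formative list, by 3.01 ± 0.09 (adjusted p = 3.09e-21). H3K27me3 rose at Hoxc12 by 3.75 ± 0.18 (adjusted p = 1.88e-15), from -1.06 ± 0.38 (n = 2) to 3.28 ± 0.33 in TET_WT. This contrast averages TET_WT and DNMT_WT, 6 libraries per stage (5 for H3K27me3 in ESC), and includes the library labelled DNMT_WT EpiLC replicate 2, which is described under the DNMT lines.

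In the naive list, H3K27ac fell at 13 of 24 measured genes and rose at none by limma (adjusted p = 2.78e-19, 1.22e-19 to 0.00321 over the alternatives), and the list held with adjusted p = 0.00321 with an estimated correlation. H3K4me3 fell at 15 of 21 naive genes (adjusted p = 9.61e-10, 4.03e-15 to 0.136 over the alternatives, adjusted p = 0.136 with an estimated correlation). In the formative list, H3K4me3 rose at 13 of 23 genes (adjusted p = 3.89e-18, 5.43e-19 to 0.00129 over the alternatives, adjusted p = 0.00129 with an estimated correlation). H3K27ac rose at 14 of 19 formative genes (adjusted p = 0.00608, 1.88e-06 to 0.746 over the alternatives, adjusted p = 0.746 with an estimated correlation). H3K27me3 passed at 1 of 11 formative genes, Foxd3, a repressor needed at this transition, by 1.19 ± 0.19. For that list the test pointed down (adjusted p = 0.0105, 0.00473 to 0.986 over the alternatives, adjusted p = 0.986 with an estimated correlation) while the median, 0.11, and the mean, 0.09, were positive. Each of these counts was the same when adjusted over the list alone.

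In wild-type EpiLC H3K27me3 rose at 19 of 36 Hox genes (adjusted p = 3.75e-12, 2.94e-16 to 0.986 over the alternatives, adjusted p = 0.986 with an estimated correlation). Hoxc13 rose by 2.77 ± 0.21. H3K27ac fell at 6 of 16 Hox genes (adjusted p = 2.91e-06, 1.84e-06 to 0.211 over the alternatives, adjusted p = 0.211 with an estimated correlation), at Hoxc12 by 2.61 ± 0.13. H3K4me3 rose at 2 and fell at 5 of 32 Hox genes, with the list test pointing up (adjusted p = 0.192), a median of -0.09 and a mean of -0.16. H3K4me3 rose at 3 of 15 neuroectoderm genes, among them Sox1, a neural transcription factor, by 1.37 ± 0.11 (list adjusted p = 2.98e-06, 1.19e-06 to 0.139 over the alternatives, adjusted p = 0.139 with an estimated correlation). In the haematopoietic and endothelial list H3K4me3 rose at 4 and fell at 1 of 15 genes (adjusted p = 0.0011, 0.000383 to 0.139 over the alternatives, adjusted p = 0.139 with an estimated correlation). Fli1, an ETS factor of blood and endothelium, rose by 1.99 ± 0.19, and Kit, a receptor of blood progenitors and germ cells, fell by 1.28 ± 0.11. H3K4me3 rose at 6 and fell at 1 of 27 imprinted genes (adjusted p = 0.000132, 0.000148 to 0.154 over the alternatives, adjusted p = 0.154 with an estimated correlation), with H19, an imprinted noncoding RNA, higher by 2.18 ± 0.15. Among 4 measured fibroblast (feeder) genes H3K27ac rose at Twist1 and fell at Pdgfrb (adjusted p = 0.0212, 0.0145 to 0.236 over the alternatives, adjusted p = 0.159 with an estimated correlation), so the fibroblast genes did not move together.

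Outside the lists, H3K4me3 rose at Wt1, a transcription factor of kidney and gonad, by 3.62 ± 0.11, and at Arih2, a ubiquitin ligase, it fell by 4.48 ± 0.20. H3K27ac rose at Foxr2 by 4.04 ± 0.16 and at Tmem154 by 4.02 ± 0.15. At Accsl it fell by 4.43 ± 0.18 and at the lectin gene Clec4a1 it fell by 4.32 ± 0.12. H3K4me1 rose around Car4, a carbonic anhydrase of the formative list, by 2.27 ± 0.09. The targeted gene Dnmt3b gained H3K27ac by 2.26 ± 0.10 and H3K4me1 by 1.13 ± 0.06, while H3K4me1 at Dnmt3a, higher by 0.91 ± 0.06, stayed under 1 log2 unit. In all, H3K4me1 rose in 9641 and fell in 12804 tiles, H3K4me3 in 3161 and 2878, H3K27ac in 11556 and 12838, and H3K27me3 in 1322 and 21. In the deposited values the splits were 4804 and 2142 for H3K4me3 and 6243 and 18583 for H3K27ac. Across tiles, which are not independent, the stage effects of the 2 wild-type lines correlated with r = 0.82 for H3K4me1, 0.83 for H3K4me3, 0.83 for H3K27ac, 0.61 for H3K27me3 and 0.35 for CTCF.

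In ESC, loss of the TET enzymes was compared with TET_WT to ask what chromatin needs demethylation in naive cells. Among genes of the lists, the largest rise in H3K27me3 was at Olig1 and Olig2, adjacent neural transcription factors. H3K27me3 at Olig1 (chromosome 16, 91268001 to 91274000) rose by 3.11 ± 0.22 (adjusted p = 6.62e-11), from -0.79 ± 0.16 (n = 2) to 2.32 ± 0.08 (n = 3). At Olig2 (91222001 to 91228000) it rose by 2.80 ± 0.24, while H3K4me3 there fell by 2.36 ± 0.13 (adjusted p = 2.04e-12), from 5.19 ± 0.04 to 2.83 ± 0.11. H3K4me3 fell at Hoxa10, a posterior patterning gene, by 1.74 ± 0.16, and H3K27ac there by 1.97 ± 0.14. H3K4me3 rose at Fli1 by 2.02 ± 0.27 (adjusted p = 3.6e-06) and at H19 by 2.07 ± 0.21 (adjusted p = 9.83e-08).

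H3K27ac fell at 8 of 16 Hox genes in TET_KO ESC (adjusted p = 2.91e-06, 1.34e-07 to 0.211 over the alternatives, adjusted p = 0.211 with an estimated correlation), and H3K27me3 rose at 7 of 36 (adjusted p = 0.000737, 7.97e-08 to 0.986 over the alternatives, adjusted p = 0.986 with an estimated correlation). Hoxc5 gained H3K27me3 by 1.92 ± 0.25 and Hoxc12 by 1.91 ± 0.27. The neuroectoderm list had H3K4me3 up at 3 and down at 3 of 15 genes, so Olig1 and Olig2 did not stand for the list. H3K4me3 rose at 2 of 11 endoderm genes (adjusted p = 0.0109, 0.00263 to 0.154 over the alternatives, adjusted p = 0.154 with an estimated correlation). At 2 of 12 mesoderm genes H3K4me3 rose, 1 of them Hand1, a heart and trophoblast factor, by 1.21 ± 0.16. H3K4me3 rose at 2 of 15 haematopoietic and endothelial genes without a list result past the threshold (adjusted p = 0.0602). Germline genes with CpG-rich promoters had lower H3K27me3 as a list of 7 (adjusted p = 0.00171, 2.92e-05 to 0.905 over the alternatives, adjusted p = 0.905 with an estimated correlation). H3K4me3 rose at Sycp3, a meiotic chromosome protein of that list, by 1.25 ± 0.26. For 2-cell-like H3K4me1, TET_KO against TET_WT in ESC, 1 of 5 genes rose, Spz1, by 1.14 ± 0.20 (list adjusted p = 0.0365, 0.000355 to 0.434 over the alternatives, adjusted p = 0.434 with an estimated correlation), and the list result was lost without TET_WT ESC replicate 2 (adjusted p = 0.051). None of the 19 housekeeping genes passed for H3K27ac in limma (0 genes), and the list stood at adjusted p = 0.983. The number of genes at an unadjusted p under 0.05 was 4307 of 9699.

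The largest falls in H3K27ac in TET_KO ESC were at H2bc14, a histone gene, by 2.63 ± 0.12 and at Spire2, an actin nucleator, by 2.52 ± 0.13, which was -2.0 with each chromosome centred since Spire2 lies on chromosome 8. The CTCF-library reads were lower too, at Spire2 (-0.97) and at H2bc14 (-0.52). H3K4me3 fell at Tspoap1 by 3.01 ± 0.22. Tdh, on chromosome 14, lost H3K4me3 by 1.55 ± 0.17 and H3K27ac by 1.11 ± 0.10, values that were -1.20 and -0.75 with each chromosome centred, so that the H3K27ac value no longer passed. H3K27me3 fell at Rgcc, a cell-cycle regulator on chromosome 14, by 1.68 ± 0.18 (-1.36 centred) and at Nos1, a nitric oxide synthase, by 1.32 ± 0.18, and rose at Nkx1-2, an axial progenitor factor, by 3.14 ± 0.25. H3K4me1 fell around Zfp697 by 2.18 ± 0.14 and rose around H2-T3, a histocompatibility gene, by 2.73 ± 0.20, and H3K27ac rose at Ubd by 2.91 ± 0.15. Some risen loci also had more CTCF-library reads in tiles without CTCF enrichment, a measure of the DNA that open chromatin can affect too. The log2 difference of those reads was 0.74 at H2-T3, 0.96 at Speer4a and 1.01 at Zfp729b, whose H3K4me3 rose by 2.94 ± 0.24. Around Speer4a H3K4me1 rose by 2.51 ± 0.38.

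In all, TET_KO ESC had 3787 tiles higher and 2528 lower in H3K4me1, 3352 and 1267 in H3K4me3, 3526 and 2571 in H3K27ac, and 713 and 782 in H3K27me3. Quantile normalization gave 3356 and 3433 for H3K4me1 and 2424 and 2300 for H3K4me3, and the deposited values gave 1310 and 7675 for H3K27ac, so which direction held more tiles depended on the scaling. The total for H3K27me3, 1495, was 672 without TET_WT ESC replicate 1 and 562 without replicate 3, each of which leaves 1 library in that group. Of the tiles higher in H3K4me1, 10.1% lay at gene ends and 50.9% outside genes, against 25.6% and 31.5% of all tested tiles. At the gene level, 312 rose and 30 fell for H3K4me1, 170 and 152 for H3K4me3, 56 and 129 for H3K27ac, and 60 and 6 for H3K27me3.

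In EpiLC, TET_KO was compared with TET_WT to ask whether demethylation matters for leaving naive pluripotency. Naive genes carried less active chromatin in the knockout. H3K4me3 at Nanog, a core pluripotency factor (chromosome 6, 122704001 to 122710000), fell by 2.09 ± 0.15 (adjusted p = 2.82e-10), from 3.82 ± 0.27 to 1.73 ± 0.14. At Fbxo15, an ESC marker (chromosome 18, 84932001 to 84938000), H3K4me3 fell by 2.08 ± 0.20 (adjusted p = 1.71e-08) and H3K27ac by 1.82 ± 0.09 (adjusted p = 8.84e-15). H3K27ac at Jam2, a junction protein of the naive list, fell by 2.24 ± 0.15 (adjusted p = 2.22e-12), from 3.21 ± 0.29 to 0.97 ± 0.19. H3K27me3 rose at Gbx2, a transcription factor of naive self-renewal (chromosome 1, 89928001 to 89934000), by 2.44 ± 0.20 (adjusted p = 8.56e-10).

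In the naive list, H3K27ac fell at 9 of 24 genes in TET_KO EpiLC (adjusted p = 7.65e-13, 7.16e-14 to 0.0133 over the alternatives), and the list held with adjusted p = 0.0133 with an estimated correlation. The H3K27ac libraries differed in enrichment by genotype, with a contrast of tested over other tiles of 2.18 to 2.29 in TET_KO EpiLC and 2.84 to 2.97 in TET_WT EpiLC, and 2.64 to 2.82 and 3.31 to 3.73 in ESC. Under quantile normalization, which gives all libraries the same distribution, the list had adjusted p = 7.16e-14. H3K4me3 fell at 8 of 21 (adjusted p = 8.31e-06, 2.62e-08 to 0.154 over the alternatives, adjusted p = 0.154 with an estimated correlation) and H3K4me1 at 2 of 25, Zfp42 and Nr0b1 (adjusted p = 4.32e-06, 2.34e-06 to 0.621 over the alternatives, adjusted p = 0.621 with an estimated correlation). Zfp42 (Rex1), a naive marker on chromosome 8, lost H3K27ac by 1.79 ± 0.13, H3K4me3 by 1.42 ± 0.20 and H3K4me1 by 1.55 ± 0.11. With each chromosome centred these were -1.20, -0.90 and -1.0, and the CTCF-library reads at Zfp42 were lower by 1.05 as well (-1.05). The formative list did not pass for H3K4me3 (1 gene higher and 1 lower of 23, adjusted p = 0.124), and Zic5, a neural and primed-state factor on chromosome 14, had H3K27ac lower by 1.14 ± 0.11, which was -0.70 with each chromosome centred. The CTCF-library reads at Zic5 were lower by 0.90 (-0.90).

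**Figure D3:**
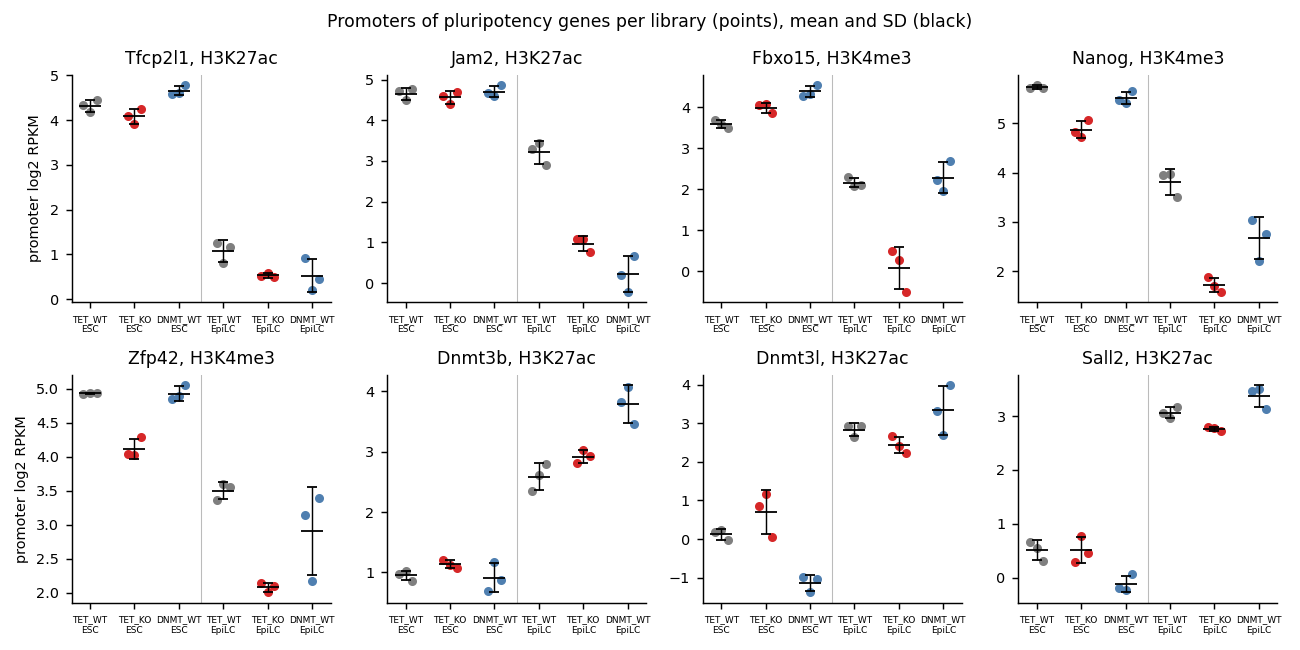
Promoter log2 RPKM of naive genes (Tfcp2l1, Jam2, Fbxo15, Nanog, Zfp42) and formative genes (Dnmt3b, Dnmt3l, Sall2) per library (points), with mean and SD (black), in TET_WT, TET_KO and DNMT_WT as ESC and EpiLC. In EpiLC, Jam2 H3K27ac stood at 3.21 in TET_WT and 0.97 in TET_KO, and Nanog H3K4me3 at 3.82 and 1.73.

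The Hoxa cluster on chromosome 6, chosen after its values were seen, is mapped for TET_KO EpiLC. H3K27me3 passed as higher in 27 of its 49 tested tiles between 52156001 and 52278000, with a median of 1.30 over the tiles, and in 0 as lower by limma. Under quantile normalization, a check also chosen after the values were seen, 6 of the 49 passed, with a median of 0.48. H3K27ac fell in 16 of 31 tiles (median -1.07) and H3K4me3 in 9 of 36 (median -0.64), with 0 rising in either, and under quantile normalization in 14 and 9. H3K4me1 passed in 0 of 57 tiles by limma (median -0.32). Over all tested tiles of chromosome 6 the medians were -0.40 for H3K4me3, -0.24 for H3K27ac, -0.21 for H3K4me1 and -0.06 for H3K27me3. Part of the lower values in the cluster thus went with the whole chromosome. H3K27me3 at Hoxa10 rose by 2.02 ± 0.26 (adjusted p = 1.36e-06), from 1.89 ± 0.17 to 3.90 ± 0.33, and no longer passed under quantile normalization, at 0.96 ± 0.18 (adjusted p = 0.000583), since the difference was under 1 log2 unit. H3K4me3 there fell by 2.26 ± 0.16, H3K27ac by 2.18 ± 0.14, and the CTCF-library reads by 0.72 (-0.72). Over all clusters, H3K27me3 rose at 17 of 36 Hox genes (list adjusted p = 0.202) and H3K27ac fell at 7 of 16 (adjusted p = 0.000289, 7.17e-05 to 0.378 over the alternatives, adjusted p = 0.378 with an estimated correlation). For H3K4me3, 1 Hox gene rose and 5 fell of 32, with the list test pointing up (adjusted p = 0.141), a median of 0.05 and a mean of -0.10.

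**Figure D4:**
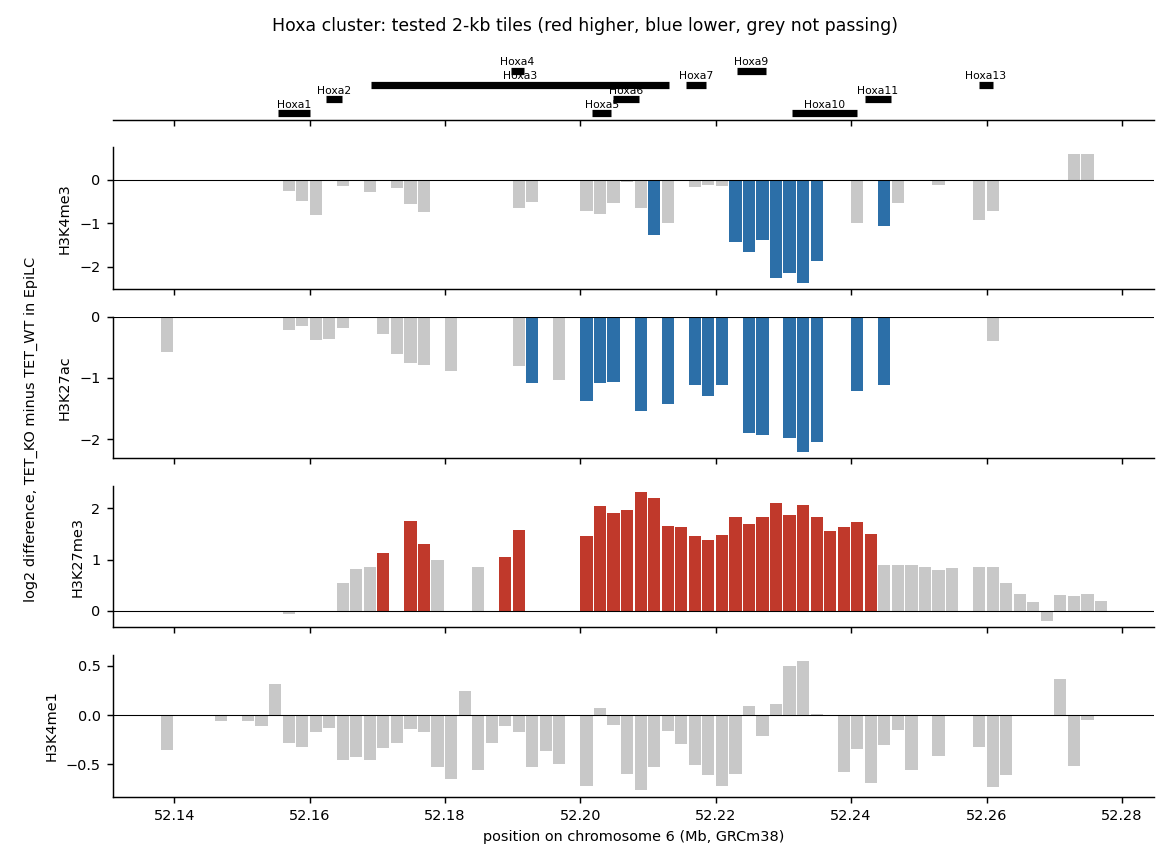
Log2 difference of TET_KO minus TET_WT in EpiLC for tested 2-kb tiles of the Hoxa cluster against the position on chromosome 6 (Mb, GRCm38), with genes above and a panel per histone mark (red higher, blue lower, grey not passing). H3K27me3 was higher in 27 of 49 tiles, and H3K27ac lower in 16 of 31.

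H3K27me3 rose at further developmental genes in TET_KO EpiLC. Olig1 rose by 3.08 ± 0.20 (adjusted p = 5.4e-12) and Olig2 by 2.49 ± 0.22, while their H3K4me3 fell by 1.67 ± 0.22 and 1.83 ± 0.13. H3K27me3 rose at 5 of 20 neuroectoderm genes (adjusted p = 0.0372, 0.0231 to 0.986 over the alternatives, adjusted p = 0.986 with an estimated correlation), 4 of 17 haematopoietic and endothelial genes (adjusted p = 0.969), 3 of 10 endoderm genes (adjusted p = 0.887), 2 of 16 mesoderm genes (adjusted p = 0.574) and 2 of 9 trophoblast genes (adjusted p = 0.906). In the haematopoietic, endoderm and trophoblast lists the test pointed down while the medians, 0.77, 0.83 and 0.64, and the means, 0.67, 0.68 and 0.60, were positive. These rises depended on the scaling. Under quantile normalization Sox17, an endoderm and endothelial factor, moved from 1.35 ± 0.28 to 0.40, Eomes, a mesendoderm and trophoblast factor, from 1.24 ± 0.19 to 0.31, Gata6, an endoderm factor, from 1.21 ± 0.22 to 0.33, and Foxd3 from 1.40 ± 0.25 to 0.44, and none of these passed. Olig1 and Gbx2 passed there, at 1.96 and 1.44 or more. H3K27me3 at Prkce, a protein kinase, rose by 2.52 ± 0.18.

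H3K4me3 was tested over the same lineage lists in TET_KO EpiLC. It was higher over 12 mesoderm genes (0 passing by limma on their own, median 0.47, adjusted p = 0.000562, 6.68e-06 to 0.139 over the alternatives, adjusted p = 0.139 with an estimated correlation). It rose at 2 of 15 haematopoietic and endothelial genes, Fli1 and Gfi1 (adjusted p = 0.00794, 0.000822 to 0.139 over the alternatives, adjusted p = 0.139 with an estimated correlation). It rose at 3 and fell at 3 of 15 neuroectoderm genes (adjusted p = 5.66e-05, 1.57e-07 to 0.154 over the alternatives, adjusted p = 0.154 with an estimated correlation). Cdx2, the trophoblast determinant, gained H3K4me3 by 1.41 ± 0.20. Among 4 targeted genes H3K4me3 fell at 2, Tet1 by 1.17 ± 0.10 and Tet2 by 1.18 ± 0.26 (list adjusted p = 0.165). Tet1 was -0.82 under quantile normalization, and Tet2 H3K4me3, TET_KO against TET_WT in EpiLC, was -0.82 without TET_KO EpiLC replicate 3, so neither passed there. The imprinted list had 1 gene higher and 1 lower of 27 in H3K4me3, with a test pointing up (adjusted p = 0.0156, 0.000532 to 0.292 over the alternatives, adjusted p = 0.292 with an estimated correlation), a median of -0.04 and a mean of 0.11. H3K4me1 rose around Peg13, an imprinted noncoding RNA, by 1.45 ± 0.14 and around Pax7, a neural crest and muscle factor, by 1.1 ± 0.12.

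The largest falls in H3K27ac in TET_KO EpiLC were at Vegfc, a lymphatic growth factor on chromosome 8, by 2.76 ± 0.13 (-2.18 with each chromosome centred), where the CTCF-library reads were lower as well (-1.16), and at Cobl, an actin nucleator, by 2.47 ± 0.18. H3K4me3 fell at Tspoap1 by 3.15 ± 0.22 and at the cytokine gene Il34, on chromosome 8, by 2.51 ± 0.19 (-1.99 centred). H3K27ac rose at Aurkc, a meiotic kinase, by 1.99 ± 0.21, where CTCF-library reads were higher by 1.32, and at Zfp729b by 2.67 ± 0.18, where they were higher by 1.0. H3K4me1 rose around H2-T3 by 3.00 ± 0.20, with these reads higher by 0.83, and fell around Zfp951 by 2.00 ± 0.12, where the CTCF-library reads were lower (-0.73). In all, 4762 tiles rose and 5586 fell in H3K4me1, 1553 and 3329 in H3K4me3, 1908 and 4788 in H3K27ac, and 3434 and 569 in H3K27me3. The deposited values gave 2633 and 9461, 2767 and 2409, 614 and 10101, and 1099 and 1776 in that order, and quantile normalization gave 1977 and 2368 for H3K4me3 and 362 and 471 for H3K27me3. The H3K27me3 total of 4003 was 2177 without TET_KO EpiLC replicate 3. Of the tiles higher in H3K27me3, 66.1% lay at gene ends, against 23.0% of all tested tiles, and of those lower in H3K27ac 53.6% lay outside genes, against 30.6%. At the gene level 568 rose and 5 fell for H3K27me3, 107 and 327 for H3K4me3, 51 and 126 for H3K27ac, and 253 and 90 for H3K4me1.

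TET_KO effects in the 2 stages were related across tiles, with r = 0.59 for H3K4me1, 0.74 for H3K4me3, 0.54 for H3K27ac and 0.69 for H3K27me3. For H3K4me3, 1147 tiles rose in both stages, against 135.6 if the calls were independent, and for H3K27me3 480 rose in both, against 46.4. Both stages compare the same 2 single lines, so a fixed difference between their genomes recurs in both. The stages are thus not independent tests of the genotype. The effect in EpiLC was also compared with the stage effect of DNMT_WT, which shares no libraries with it but includes the libraries labelled DNMT_WT EpiLC replicate 2. For H3K4me3, 1577 tiles were lower in both, against 303.1 (r = 0.46), and for H3K27me3 475 were higher in both, against 79.5 (r = 0.39). For H3K27ac 2044 were lower in both, against 981 (r = 0.17). The H3K4me3 effect in TET_KO ESC also went with that stage effect, with 1534 tiles higher in both against 360.1 (r = 0.44). These overlaps with the stage effect were not repeated under quantile normalization for H3K4me3 and H3K27me3. The balance of higher and lower tiles in TET_KO moved there for both marks. What the H3K4me3 and H3K27me3 overlaps hold beyond scaling was therefore not settled. Between the effects of TET_KO and DNMT_KO r ran from -0.09 to 0.16 over the targets and stages, where the values for EpiLC include the libraries labelled replicate 2 of the DNMT lines. Some calls were shared beyond independence in either direction. In ESC, 20 H3K27ac tiles were higher in both, against 6.1, and 14 were lower in TET_KO and higher in DNMT_KO, against 4.5. For H3K4me3 in ESC these were 13 against 4.9 and 7 against 1.8, and for H3K4me1 in EpiLC 35 against 21.7 and 58 against 25.5.

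CTCF changed in few tiles. Its libraries varied in enrichment within groups. The contrast of tested over other tiles was 1.158 to 2.675 in TET_WT ESC and 0.83 to 1.867 in TET_KO ESC. In EpiLC it was 2.129 to 2.989 in TET_WT and 1.037 to 2.365 in TET_KO. Such spread limits what can pass, so few calls do not show that CTCF binding was stable. In TET_KO ESC 185 tiles rose and 77 fell, and in EpiLC 174 and 137, with r = 0.63 between the stages. The deposited values gave 37 and 39 in ESC and 41 and 1445 in EpiLC, quantile normalization 152 and 156 in ESC, and centring each chromosome 143 and 34 in ESC and 156 and 60 in EpiLC. The total of 311 in EpiLC was 475 without TET_KO EpiLC replicate 1. The largest rise in both stages was on chromosome 12 at 18514001 to 18516000, in 5730507C01Rik, by 6.30 ± 0.28 in ESC (adjusted p = 1.79e-27), from -4.20 ± 0.77, near the floor of an empty tile, to 2.10 ± 0.58. A stretch on the same chromosome at 18562001 to 18568000 lacked reads in TET_WT (7 scaled reads, against 197.6 in TET_KO), so DNA missing from TET_WT was not separated from a gain of CTCF there. The largest fall was on chromosome 14 at 53044001 to 53046000, by 4.04 ± 0.37 in ESC and 3.81 ± 0.37 in EpiLC. In ESC it went from 1.12 ± 0.30 to -2.91 ± 1.03. The TET_KO value lay below the medians of those libraries over all tiles, -0.331 to -0.228 before the shift. DNA missing from TET_KO was thus not separated from a loss of CTCF there. In EpiLC the tile at 123308001 to 123310000 on chromosome 8, in Fanca, a DNA repair gene next to Spire2, fell by 3.66 ± 0.21 (adjusted p = 3.37e-21), from 2.82 ± 0.16 to -0.84 ± 0.54. Between stages in wild type 4 tiles rose and 4 fell, among them a fall by 1.2 ± 0.12 in Stab2, a scavenger receptor gene, and a rise by 1.22 ± 0.17 near Dysf, a membrane repair gene. Without TET_WT ESC replicate 1 the total of 8 was 14, and the deposited values gave 217 higher and 0 lower, limma calling 0 of the latter.

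In ESC, DNMT_KO was compared with DNMT_WT to ask what DNA methylation restrains in naive cells, where methylation is low. The largest change was at Uty, a histone demethylase gene of chromosome Y. Uty H3K27ac, DNMT_KO against DNMT_WT in ESC, rose by 2.67 ± 0.47 (adjusted p = 0.00659), from -3.05 ± 0.50 to -0.38 ± 0.21, and did not pass without DNMT_WT ESC replicate 1 (2.39) or without DNMT_KO ESC replicate 2 (2.60). H3K4me1 rose around Tmem267 on chromosome 13 by 1.58 ± 0.24 (adjusted p = 0.00335), from 0.43 ± 0.66 to 2.01 ± 0.11. No member of any of the 14 lists passed in limma in this comparison, and Hox genes had slightly lower H3K4me3 as a list (0 of 32 passing, median -0.11, adjusted p = 0.000132, 1.18e-06 to 0.204 over the alternatives, adjusted p = 0.204 with an estimated correlation). At an unadjusted p under 0.05 there were 359 H3K4me3 genes of 10927.

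The tiles that changed in DNMT_KO ESC almost all rose, with 30 higher and 0 lower in H3K4me1, 56 and 0 in H3K4me3, 136 and 5 in H3K27ac, 13 and 1 in H3K27me3 and 0 and 1 in CTCF. For H3K27me3 the deposited values gave 11 and 559 and quantile normalization 43 and 50, so its direction depended on the scaling. All DNMT_KO ESC libraries of H3K27me3 were less enriched than the DNMT_WT ones. Their contrasts of tested over other tiles were 0.585 to 1.147, against 1.348 to 1.451. H3K27me3 thus does not add to the rise seen in the other histone marks. The fit shares an estimate of spread over the 8 groups, so the libraries labelled replicate 2 of DNMT EpiLC enter these totals too. With those libraries left out, a choice made after seeing the data, the ESC totals of H3K4me1, H3K4me3 and H3K27me3 were larger. Their values are given with the dependence on processing. Single libraries of the comparison also moved these totals. H3K4me1 was 17 without DNMT_WT ESC replicate 2 and 17 without DNMT_KO ESC replicate 3. H3K4me3 was 19 and 21 without DNMT_WT ESC replicates 1 and 2, and 15, 18 and 25 without DNMT_KO ESC replicates 1, 2 and 3. H3K27ac was 84 without DNMT_WT ESC replicate 1. H3K27me3 was 4 without DNMT_WT ESC replicate 3, and 0, 51 and 47 without DNMT_KO ESC replicates 1, 2 and 3. The CTCF tile, on chromosome 9 at 124456001 to 124458000, fell by 1.13 ± 0.20 (adjusted p = 0.031) and was lost without any single library of this comparison. Among genes, 6 rose for H3K4me1 and 4 for H3K27ac, while 0 passed in limma for H3K4me3 and H3K27me3, with 359 and 236 at an unadjusted p under 0.05.

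In EpiLC, where wild-type cells gain DNA methylation, DNMT_KO was compared with DNMT_WT. Tiles were chosen from ESC alone, outside chromosome Y, where all 3 DNMT_KO libraries exceeded all 3 DNMT_WT libraries and the means differed by at least 1 log2 unit, without a limma call. Over the 225 such tiles for H3K4me3, the library labelled DNMT_WT EpiLC replicate 2 stood at 1.15, beside -0.29 and -0.20 for replicates 1 and 3, and the library labelled DNMT_KO EpiLC replicate 2 stood at -0.30, beside 0.99 and 1.38. Over 203 such tiles H3K27ac of the libraries labelled replicate 2 was 0.73 in DNMT_WT and 0.19 in DNMT_KO, beside 0.18 and 0.29, and 0.77 and 0.94. Over 93 such tiles H3K27me3 was 0.18 and -0.19, beside -0.39 and -0.19 in DNMT_WT, and -0.11 and 0.11 in DNMT_KO. For H3K4me1 (58 tiles) only the library labelled DNMT_KO EpiLC replicate 2 was out of place, at -0.05 beside 0.58 and 0.59. The H3K4me1 libraries also differed in enrichment. The contrast of tested over other tiles was 1.0 and 1.56 for DNMT_KO EpiLC replicates 1 and 3, against 3.17 for the library labelled replicate 2 and 3.21 to 3.45 in DNMT_WT. For H3K27ac the contrast was 2.95 for the library labelled DNMT_WT EpiLC replicate 2, beside 3.2 and 3.25, and 3.32 for the library labelled DNMT_KO EpiLC replicate 2, beside 2.37 and 2.91. For H3K4me3 it was 8.47 for the library labelled DNMT_WT EpiLC replicate 2, beside 8.53 and 7.41. In the inputs, reads over chromosome Y genes relative to autosomes were -1.45 for the library labelled DNMT_WT EpiLC replicate 2, beside -1.68 and -1.83, and -1.69 for the library labelled DNMT_KO EpiLC replicate 2, beside -1.40 and -1.46. All labels were kept as given, so every direction in DNMT EpiLC below rests on groups that hold these libraries, except where they are left out.

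**Figure D5:**
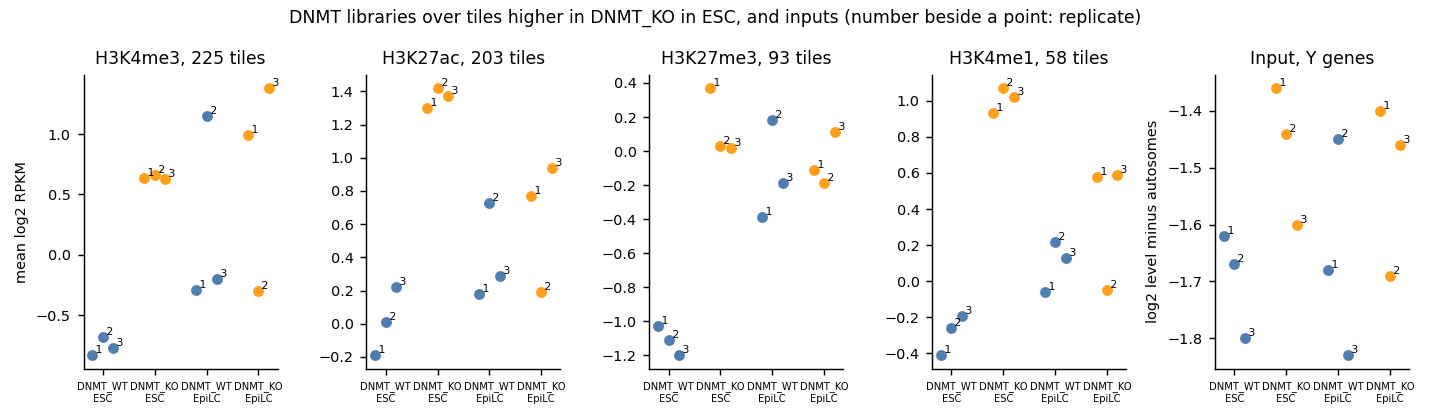
Mean log2 RPKM per DNMT library over tiles outside chromosome Y whose DNMT_KO ESC libraries all exceeded the DNMT_WT ESC libraries, with means at least 1 log2 unit apart (225, 203, 93 and 58 tiles for H3K4me3, H3K27ac, H3K27me3 and H3K4me1), and input level over chromosome Y genes minus autosomes, with DNMT_WT in blue, DNMT_KO in orange and the replicate number beside each point. In EpiLC the H3K4me3 libraries labelled replicate 2 stood at 1.15 in DNMT_WT and -0.30 in DNMT_KO.

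With the labels as given, no gene passed in DNMT_KO EpiLC by limma for any histone mark (0 genes), with 4218, 320, 345 and 115 genes at an unadjusted p under 0.05 for H3K4me1, H3K4me3, H3K27ac and H3K27me3. Tiles passed for H3K4me1, 570 higher and 3 lower, and in 0 tiles for CTCF, H3K4me3, H3K27ac and H3K27me3 by limma, with 522, 549, 3505 and 4899 at an unadjusted p under 0.05. The deposited H3K4me1 values gave 22 and 10486. With low-enrichment libraries left out, a choice made after seeing the data that keeps only the library labelled replicate 2 in the DNMT_KO EpiLC group, 0 H3K4me1 tiles were higher and 8 lower by limma, with 4821 at an unadjusted p under 0.05. The lone library is assumed there to vary like the other groups. The H3K4me1 total of 573 was 951 without DNMT_WT EpiLC replicate 3, and 5, 3123 and 184 without the libraries labelled DNMT_KO EpiLC replicates 1, 2 and 3. H3K4me3 was 29 without the library labelled DNMT_WT EpiLC replicate 2 and 31 without that labelled DNMT_KO EpiLC replicate 2. H3K27ac was 148 and 58 without these, and 4 without DNMT_WT EpiLC replicate 3, and H3K27me3 was 256 and 76, and 1 without DNMT_WT EpiLC replicate 3. CTCF was 1 without DNMT_KO EpiLC replicate 3. The Hox list had slightly lower H3K4me3 (0 of 32 genes passing by limma, median -0.10, adjusted p = 2.64e-08, 1.5e-17 to 0.139 over the alternatives, adjusted p = 0.139 with an estimated correlation), and 320 of 10927 genes had an unadjusted p under 0.05.

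When the libraries labelled replicate 2 of both genotypes were left out, a choice made after seeing the data, 3019 tiles were higher and 306 lower in H3K4me1, 1439 and 228 in H3K4me3, 966 and 184 in H3K27ac, and 1024 and 384 in H3K27me3, with 2 libraries per group. The H3K4me1 counts rest on the 2 low-enrichment DNMT_KO libraries, with contrasts of 1.0 and 1.56 against 3.21 and 3.35 in DNMT_WT. CTCF had 0 calls by limma under this setting too. The genes named next were chosen after their values were seen. H3K4me3 rose at the chromosome Y genes Uty by 3.38 ± 0.34, Eif2s3y by 3.35 ± 0.31 and Ddx3y by 2.06 ± 0.32, and at Dlx3, a homeobox factor of skin and trophoblast, by 1.41 ± 0.19. H3K27me3 rose at Nog, a BMP antagonist, by 1.31 ± 0.21, at Sox17 by 1.25 ± 0.19, at Sox1 by 1.17 ± 0.20 and at Sox18, an endothelial factor, by 1.28 ± 0.19, and H3K4me3 at Sox18 fell by 1.11 ± 0.22. In all, 98 genes rose and 3 fell for H3K4me1, 28 and 4 for H3K4me3, 10 and 3 for H3K27ac and 68 and 1 for H3K27me3.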

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

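The tests of a wrong label and of depth in DNMT EpiLC, of copy number and depth in TET_KO, and both tests of the direction of H3K27me3 were chosen only after the result was seen. The other tests, including the other splits of the libraries, were chosen before.

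Many effects of TET_KO differed between EpiLC and ESC in a test of the difference itself, in 5528 tiles for H3K4me1, 2752 for H3K4me3, 6192 for H3K27ac and 21 for H3K27me3. The share in which the effect was more positive in EpiLC was 9.2% for H3K4me3 but 53.3% under quantile normalization, and 43.0% for H3K4me1 but 23.3% in the deposited values. For H3K27me3 it was 61.9%, with 6 more positive and 32 more negative tiles under quantile normalization and 0 and 8 in the deposited values. For DNMT_KO the difference passed in 3 H3K4me1 tiles and 24 H3K27ac tiles, with the libraries labelled replicate 2 of DNMT EpiLC included.

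Among named genes, the TET_KO effect in EpiLC minus that in ESC passed in both directions. For H3K4me3 it was -2.48 at Fbxo15, -1.22 at Nanog, -1.30 at Il34, -1.18 at Tet1 and -1.08 at H19. For H3K27ac it was -2.15 at Jam2, -1.97 at Fbxo15, -1.96 at Ubd, -1.86 at Vegfc, -1.84 at Cobl and -1.08 at Zfp42, and 1.1 at H2bc14 and 1.11 at Spire2. For H3K4me1 it was -1.20 at Nr0b1 and -1.17 at Zfp951. For H3K27me3 it was 2.21 at Rgcc, 1.67 at Gbx2, 1.63 at Nos1 and 1.57 at Tfap2c, and -1.93 at Nkx1-2 and -1.17 at Ccdc194. Tet1 H3K4me3 went opposite ways between the stages in the 2 wild-type lines, by 0.58 in TET_WT and -0.38 in DNMT_WT, a difference that was not tested.

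Reads outside the tested comparisons also differed. In the CTCF libraries, 428 tiles had at least 50 pooled reads in TET_KO and at most 3 in TET_WT at equal depth, and 168 tiles the reverse, while between DNMT_WT and DNMT_KO both counts were 0 without a limma test. The longest stretch covered 43 tiles, 86 kb on chromosome 6 from 89090001 to 89176000, with 4712 scaled reads in TET_WT and 33.9 in TET_KO. Stretches of 16 tiles on chromosome 13 (68522001 to 68554000) and chromosome 8 (73998001 to 74030000) were missing in TET_WT. Between the 2 wild-type lines 236 tiles lacked reads in DNMT_WT alone and 222 in TET_WT alone. TET_KO thus held reads where TET_WT had almost none, so TET_WT is not taken here as its direct parent. Changes in TET_KO were not separated from other differences between these lines.

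In DNMT EpiLC the libraries labelled replicate 2 lay on the side of the other genotype. Depth was argued against, since the H3K4me3 library labelled DNMT_WT replicate 2 stood 1.44 log2 units above replicate 1 over the same tiles at depths of 30.8 and 30.9 (1e6 reads). An exchange of labels stays open as a candidate explanation, since both libraries were out of place in 3 of 5 targets (H3K4me3, H3K27ac and H3K27me3). For CTCF only 2 tiles were available, too few to decide. The differences in enrichment between these libraries, given under the DNMT lines, were not tested as a cause. Inputs over 8 chromosome Y genes, a test chosen before, gave 0.24 for the library labelled DNMT_WT EpiLC replicate 2 minus that labelled DNMT_KO EpiLC replicate 2, against -0.32 for the means of the other replicates. Over these genes the CTCF library labelled DNMT_WT EpiLC replicate 2 stood at -2.05, beside -1.87 and -1.82. That labelled DNMT_KO EpiLC replicate 2 stood at -1.83, beside -2.07 and -2.22. Each lay with the other genotype, though the genotypes differed there in the opposite direction to the inputs. No biological explanation was tested.

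Many tiles changed in TET_KO. Copy number of whole chromosomes was argued against as the sole cause, since 5319 H3K27ac tiles in ESC passed with each chromosome centred, beside 6097. Segments present in a single line were argued against for most tiles, since 3.8% of called histone tiles moved by 1 log2 unit the same way in CTCF-library reads, beside 0.9% of uncalled tiles. Depth stays open, since the depths of the genotypes overlapped in 6 of the 8 marks and stages but in H3K27ac ESC only from 78.4 to 78.9 (1e6 reads), and no fit at equal depth was made. The TET genotype and other differences between these single lines stay open, as does the lower enrichment of all TET_KO H3K27ac libraries, although 8508 H3K27ac tiles passed in EpiLC under quantile normalization, beside 6696.

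H3K27me3 was higher in most of the tiles that changed in TET_KO EpiLC, 85.8% of them. Scaling between libraries is a candidate explanation for that direction, since 43.5% were higher under quantile normalization and 38.2% in the deposited values. Better enrichment in the knockout libraries stays open, since 2 measures of it point opposite ways. The lowest TET_KO contrast of tested over other tiles minus the highest TET_WT contrast was -0.59, with 1.77 to 1.98 in TET_KO and 1.90 to 2.36 in TET_WT, but the top 1% of tiles held 10.0% to 14.9% of the signal in TET_KO and 7.28% to 10.3% in TET_WT. Whether total H3K27me3 differs between the genotypes, a biological explanation, cannot be read from these values and was not tested.

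The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. In 1 of 10 splits, the real one, as many tiles passed for each TET_KO comparison of 3 against 3 and for each DNMT_KO comparison in ESC. In TET_KO ESC the real count and the highest other were 262 and 13 for CTCF, 6315 and 0 for H3K4me1, 4619 and 0 for H3K4me3 and 6097 and 0 for H3K27ac. In TET_KO EpiLC they were 311 and 0 for CTCF, 10348 and 1 for H3K4me1, 4882 and 0 for H3K4me3, 6696 and 0 for H3K27ac and 4003 and 0 for H3K27me3. In DNMT_KO ESC they were 1 and 0 for CTCF, 30 and 1 for H3K4me1, 56 and 0 for H3K4me3, 141 and 0 for H3K27ac and 14 and 8 for H3K27me3.

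In DNMT_KO EpiLC 10 of 10 splits gave as many tiles as the real one for CTCF (0, highest other 2), H3K4me3 (0 and 1805), H3K27ac (0 and 1044) and H3K27me3 (0 and 1225), limma calling 0 tiles for the real split of each. With a real count of 0 every split gives as many, so the share says nothing for these 4 targets. For H3K4me1 4 of 10 did (573 and 1224). For H3K4me3, H3K27ac and H3K27me3 the split with the highest count exchanged the libraries labelled replicate 2 of the 2 genotypes, which points to a structure of the samples other than the labels. For EpiLC against ESC in wild type, 1 of 100 splits, the real one, gave as many tiles for each target. This share is under 0.05 and is the lowest that 100 splits allow. It covers the spread between these libraries, which the labels do not call separate cultures. The real counts and highest others were 8 and 1 for CTCF, 22445 and 10201 for H3K4me1, 6039 and 2987 for H3K4me3, 24394 and 15378 for H3K27ac and 1343 and 633 for H3K27me3.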

How the results depend on the processing

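The alternatives that leave out low-enrichment libraries, and replicate 2 of both genotypes in DNMT EpiLC, were chosen only after the result was seen. The others were chosen before. Totals of changed tiles are given where they moved by over 1.5 times, and the cause was not tested unless stated.

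As deposited, 9 of 25 totals moved. CTCF gave 76 tiles in TET_KO ESC, 1486 in TET_KO EpiLC, 0 in DNMT_KO ESC and 217 between stages. H3K4me1 gave 7 in DNMT_KO ESC and 10508 in DNMT_KO EpiLC, H3K27ac 10715 in TET_KO EpiLC, and H3K27me3 570 in DNMT_KO ESC and 840 between stages. Quantile normalization moved 5 totals, CTCF to 0 in DNMT_KO ESC, H3K4me1 to 68 in DNMT_KO EpiLC, and H3K27me3 to 2427 in TET_KO ESC, 833 in TET_KO EpiLC and 93 in DNMT_KO ESC. Centring each chromosome moved 1, CTCF in DNMT_KO ESC, to 0.

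A pseudocount of 0.5 RPKM, which shrinks differences at low values by construction, moved 13 totals. CTCF gave 109 in TET_KO ESC, 175 in TET_KO EpiLC, 0 in DNMT_KO ESC and 1 between stages. H3K4me1 gave 3133 in TET_KO ESC, 5530 in TET_KO EpiLC and 48 in DNMT_KO EpiLC, and H3K27ac 3748 and 4241 in TET_KO ESC and EpiLC. H3K27me3 gave 738 and 2374 in TET_KO ESC and EpiLC, 0 in DNMT_KO ESC and 759 between stages.

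Without an enrichment minimum 20 totals moved, since all tiles were then tested. TET_KO ESC and EpiLC gave 1780 and 6081 for CTCF, 13228 and 43027 for H3K4me1, 62883 and 40973 for H3K27ac, 75271 and 62996 for H3K27me3, and 21594 for H3K4me3 in EpiLC. DNMT_KO ESC gave 2 for CTCF, 0 for H3K4me1, 1 for H3K4me3, 333 for H3K27ac and 94 for H3K27me3, and DNMT_KO EpiLC 0 for H3K4me1. EpiLC against ESC gave 381 for CTCF, 123332 for H3K4me1, 59756 for H3K4me3, 109464 for H3K27ac and 16083 for H3K27me3.

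With low-enrichment libraries left out 4 of 20 totals moved, CTCF to 0 in DNMT_KO ESC, H3K4me1 to 46 in DNMT_KO ESC and 8 in DNMT_KO EpiLC, and H3K27me3 to 0 in DNMT_KO ESC. With replicate 2 of both genotypes left out of DNMT EpiLC 7 moved, H3K4me1 to 49 in DNMT_KO ESC and 3325 in EpiLC, H3K4me3 to 188 and 1667, H3K27me3 to 39 and 1408, and H3K27ac to 1150 in EpiLC.

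Leaving out single libraries moved 36 of 178 totals. CTCF ranged from 300 to 475 in TET_KO EpiLC, 0 to 0 in DNMT_KO ESC, 0 to 1 in DNMT_KO EpiLC and 7 to 14 between stages. H3K4me1 ranged from 17 to 36 in DNMT_KO ESC and 5 to 3123 in DNMT_KO EpiLC, H3K4me3 from 15 to 39 and 0 to 31, H3K27ac from 84 to 191 and 0 to 148, and H3K27me3 from 0 to 51 and 0 to 256. H3K27me3 ranged from 562 to 1544 in TET_KO ESC, where a lone TET_WT library was assumed to vary like the other groups, and 2177 to 5711 in TET_KO EpiLC.

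The replicate number as a block moved 0 of the 25 totals of the limma fits by over 1.5 times, for example 259 beside 262 for CTCF in TET_KO ESC. The numbers do not pair the libraries, since the correlation of residuals exceeded 0.1 in 5 of 84 pairs for CTCF and 24 of 84 for H3K4me3.

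No named gene reversed under any alternative run. Of 248 named gene values, 222 were the same under quantile normalization, 229 as deposited, 209 with the pseudocount, 247 with the block and 248 with replicate 2 of DNMT EpiLC left out, and 223 of 247 with chromosomes centred. With single libraries left out 1905 of 1959 were. No gene passed in DNMT_KO EpiLC with all libraries, so the named genes say little about leaving out replicate 2 there. Over all genes that setting gave 98 higher and 3 lower for H3K4me1 and 28 and 4 for H3K4me3. For H3K27ac it gave 10 and 3, and for H3K27me3 68 and 1. Of 59 passing list results, 3 passed with an estimated correlation, 42 as deposited, 36 under quantile normalization, 56 with the pseudocount, 55 with chromosomes centred and 59 with the block.

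A list result pointed the other way in 3 cases, none past the threshold, and the cause was not tested. With low-enrichment libraries left out, the DNMT_KO EpiLC group of H3K4me1 keeps only the library labelled replicate 2, assumed to vary like the other groups. There formative and primed pluripotency H3K4me1, DNMT_KO against DNMT_WT in EpiLC, had adjusted p = 0.328 (7.43e-06 to 0.722 over the alternatives) and housekeeping H3K4me1, DNMT_KO against DNMT_WT in EpiLC, 0.46 (0.00477 to 0.731). Without DNMT_KO EpiLC replicate 3, neuroectoderm H3K4me3, DNMT_KO against DNMT_WT in EpiLC, had 0.815, beside 0.000174 without DNMT_KO EpiLC replicate 2 (4.31e-07 to 0.377 over the alternatives that leave out no single library).

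Depth limits tiles with few reads, and the stored 0.9 reads of an empty tile set the floor for CTCF and H3K27me3 tiles that lack reads in a line.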

Other observations

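Both tests here were chosen before the result was seen, and the repeat under quantile normalization was chosen only after.

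A smaller gain of H3K27ac in TET_KO EpiLC was tested as a hypothesis, in which tiles that gain H3K27ac on differentiation would be those lower in the knockout. Across tested tiles the TET_KO effect in EpiLC and the stage effect in DNMT_WT had r = 0.17, where the hypothesis needs a negative value. The stage effect includes the library labelled DNMT_WT EpiLC replicate 2. Tiles higher in the stage effect and lower in TET_KO numbered 548, below the 949.1 that independent lists give, while 2044 were lower in both, against 981. Enrichment was lower in TET_KO EpiLC than in TET_WT EpiLC (contrast of tested over other tiles 2.18 to 2.29 against 2.84 to 2.97) and lower in DNMT_WT EpiLC than ESC (2.95 to 3.25 against 4.19 to 4.34), which could give a positive r by itself. Under quantile normalization r was 0.27, with 449 tiles higher in the stage effect and lower in TET_KO, against 886.1. There 2415 tiles were lower in both, against 1016.7. The predicted pattern was thus not found for H3K27ac as a whole with either scaling. The test did not compare the gain in TET_KO with that in TET_WT, so a smaller gain is not excluded. Enrichment acting alike on all tiles is argued against as the sole cause of the tiles lower in both, since their excess stayed under quantile normalization. Effects of enrichment that differ between tiles stay open.

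On chromosome Y, 4 of 6 tested H3K4me3 tiles and 5 of 13 H3K27ac tiles were higher in DNMT_KO ESC. By limma 0 of 8 tiles passed there for H3K4me1, 0 of 6 for H3K27me3 and 0 of 15 for CTCF. Fewer copies of chromosome Y in DNMT_WT, as the whole cause, would lower the inputs by as much. The input difference over single-copy genes of chromosome Y was 0.23, with -1.47 ± 0.12 in DNMT_KO and -1.70 ± 0.09 in DNMT_WT (SD, n = 3 each), far under the H3K27ac difference of 2.67 ± 0.47 (SE) at Uty. In the CTCF libraries the same genes went the other way, with -1.97 ± 0.08 in DNMT_KO and -1.77 ± 0.19 in DNMT_WT. The DNA difference does not account for the change at Uty, and what does was not tested.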
